A study of Mus musculus with 12 samples.

How the data were processed

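The series labels describe bulk RNA-seq of P50 mouse prefrontal cortex (4 control and 4 hGFAP-Cre Egfr cKO samples) and droplet single-cell RNA-seq of sorted P2 dorsal cortex (1 control and 1 Egfr cKO sample). Another 2 single-cell samples at E17 were not analysed here. The labels name HISAT2 2.0.4, Cell Ranger and the builds mm10 and GRCm38, without saying which step used which. The counter, the annotation and the test behind the bulk p-values are not given in the sources used here.

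The deposited bulk table holds whole-number counts per gene and library, which were used as deposited. The authors also deposited mean FPKM per group and their own p-value and q-value per gene. Another 8 columns of FPKM per library in the deposited table were not used. FPKM per library, for 3 alternatives only, was rebuilt from the counts with each gene's constant from the group means. That constant was the same from both groups, within a relative tolerance of 1e-04, for 19280 of 21324 genes, and the reason for the others was not examined. The columns name the group but not the labelled replicate, so libraries keep their column numbers (control 9 to 12, cKO 1, 2, 3 and 5) and nothing was paired. The labels call the samples biological replicates without naming animals, so the p-values measure the spread between these samples. Replicates differed by more than sampling noise in every pair. The deposited single-cell matrices hold UMI counts per gene and barcode, made with Cell Ranger 5.0.0 per the file headers.

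P50 counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. SE is the log2 fold change divided by the square root of F, and CPM uses TMM factors. Of 21722 genes in the table, 15441 were tested. Gene lists, 36 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. On simulated counts for the 15441 genes, with 200 changed, edgeR recovered 30% of genes changed 1.5-fold, 72% of genes changed 2-fold and 98% of genes changed 4-fold, with 5 false calls. Named P50 genes were Egfr, then the called genes with a symbol, no overlap between groups and a CPM of 1 or more, at most 12 each way, then called members of lists.

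Cells with 1000 or more genes and under 10% mitochondrial UMIs were kept: 9961 in control and 5470 in cKO. Doublets were called by a simulator written for this work, which takes the highest scores in each library at 0.8% per 1000 barcodes. It removed 947 control cells (9.51%) and 283 cKO cells (5.17%), so the share removed differs between libraries by construction. Both libraries were clustered together without integration (2000 variable genes, 30 components, 15 neighbours, leidenalg 0.10.2 at resolution 1).

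Marker genes, gene lists, tests and named-gene rules were fixed before the data were examined, but the rule that turns markers into names was not. A cluster took the class with the highest mean marker log2 ratio against the other clusters (20 CPM added, mean of 0.5 or more), with at least 3 markers at 2-fold or more, unless its 10 leading genes held more markers of another class. A rule against clusters low in UMIs with no leading marker left none unnamed in the main clustering. A first version also left ties unnamed, and was replaced after the clusters had been seen. Clusters between radial glia and astrocytes, or between kinds of GABAergic neuron, were called "not told apart", which was also decided after the clusters had been seen. So was the sum of all radial glia and astrocyte clusters. The radial glia-like class was left out of gene and list comparisons, apart from values of Egfr, Prm1 and Hopx. This was decided after its cKO cells proved to come mostly from a cluster with 0 control cells. Its Egfr and Hopx ratios therefore set mostly different clusters side by side. Names are rebuilt and may differ from the study's own.

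With 1 library per genotype no test was run on P2 cells. UMIs were summed per library and class for classes with 50 or more cells in each. Ratios have exact Poisson 95% intervals and shares have exact Clopper-Pearson ones, both for counting error only. The floor for a count of 0 is 3 counts over the class. List medians were set against 10000 random lists matched on expression, using genes with 20 or more UMIs. Random members were drawn 1 by 1, so the random range ignores that members of a list can vary together. On simulated sums for 6469 genes of glial intermediate progenitors, 95.7% of intervals covered the true ratio. Named P2 genes were Egfr, then up to 6 genes each way with the largest and smallest ratio among genes with 100 or more UMIs in the class, then list members, and the text names some of these. A list of 31 p53 target genes was written after the leading genes of a cluster had been seen. Concentration of P50 genes used a two-sided Fisher's exact test on 13709 genes, with 4 times the mean CPM of other classes as the bound.

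Alternatives for P50 were DESeq2 1.42.0, other scaling factors, other filters, limma on log2 FPKM with pseudocounts of 0.1 and 1, quality weights, other thresholds and leaving out each library. Alternatives for P2 were other cell filters, no doublet removal, resolutions 0.5 and 2, thinning to 2000 UMIs, naming per cell, centring per library and other scaling. Settings added after the data had been seen were library sex as a covariate, mitochondrial genes left out, clustering without Prm1, Xist and Y-linked genes or p53 targets, tied names left out, cKO cells split by Xist and Y-linked UMIs, the cluster led by Nrgn left out, the microglia cluster without control cells left out, lists in glial intermediate progenitors under the other clusterings, and Egfr left out of the concentration test.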

Results

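The study asked what loss of the epidermal growth factor receptor gene Egfr from the hGFAP-Cre lineage does to cortical gliogenesis and to the adult prefrontal cortex. hGFAP-Cre is a transgene that recombines floxed alleles in radial glia and their descendants. The genotype label calls the controls same litters homozygote and does not say whether they carried hGFAP-Cre. If they did not, an effect of Cre or the transgene cannot be told apart from loss of Egfr in any comparison here. Bulk RNA-seq covered P50 prefrontal cortex from 4 control and 4 Egfr conditional knockout (cKO) libraries. Single-cell RNA-seq covered sorted P2 dorsal cortex, with 1 control and 1 Egfr cKO library, so the P2 differences have no replicate check. Total counts at P50 ran from 14665880 (cKO 2) to 22854754 (cKO 3). The P2 control library held 85480826 UMIs over 11886 barcodes, and the P2 cKO library held 49891405 UMIs over 6457 barcodes. After filtering, 9014 control cells with a median of 6348 UMIs and 5187 cKO cells with a median of 7281 UMIs were used. The E17 control and Map2k1/2 double knockout libraries were not analysed here.

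The first question was whether Egfr fell in the P50 cKO prefrontal cortex and which other genes changed with it. Egfr (ENSMUSG00000020122, mm10 chromosome 11, 16752203 to 16918158) averaged 19.7 ± 2.2 CPM in control and 11.1 ± 1.0 CPM in cKO (SD, n = 4 each), and all 4 cKO libraries lay below all 4 control libraries. Its log2 fold change was -0.83 ± 0.11 (SE), with an adjusted p of 0.0282 by edgeR. That adjusted p lay above 0.05 in 7 of the 8 fits that left out 1 library. Beside Egfr, 15 genes passed the same threshold among 15441 tested, so 6 genes were higher and 10 lower in cKO. This balance depended on the method, as DESeq2 gave 88 higher and 35 lower genes, and the authors' q-values under 0.05 gave 85 higher and 42 lower.

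Counts assigned to Prm1, a protamine gene of developing sperm, had the largest rise. They summed to 1 over the 4 control libraries and to 215 over the 4 cKO libraries (edgeR adjusted p = 0.000456). The ratio was 206, with a 95% counting interval of 36.6 to 8173. Whether these counts came from the Prm1 gene or from a Cre transgene that carries Prm1 sequence was not settled, as weighed below. Agt, which encodes angiotensinogen and is made by astrocytes, rose from 2.88 ± 0.62 to 12.4 ± 3.3 CPM (SD, n = 4 each; log2 fold change 2.10 ± 0.24 SE, edgeR adjusted p = 0.0123). Egfl6, a secreted EGF-repeat protein gene, rose from 0.738 to 3.40 CPM, a log2 fold change of 2.19 ± 0.20. Alox8, a lipoxygenase gene, rose from 2.00 to 4.09 CPM, a log2 fold change of 1.03 ± 0.14. The other genes that rose were the noncoding loci 2900052N01Rik and A830036E02Rik.

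Hopx, a homeodomain gene of radial glia and astrocytes, fell from 29.4 ± 7.4 to 8.58 ± 1.04 CPM (SD, n = 4 each; log2 fold change -1.77 ± 0.18 SE, edgeR adjusted p = 0.00534). The microglial chemokine gene Ccl3 had 79 counts over the control libraries and 2 over the cKO libraries, a ratio of 0.0243 with a 95% counting interval of 0.00289 to 0.0906. Fopnl, a centrosomal protein gene, fell from 27.8 to 10.4 CPM (log2 fold change -1.42 ± 0.13). Spp1, which encodes osteopontin, fell from 4.58 to 1.76 CPM (log2 fold change -1.39 ± 0.20). Tfcp2l1 fell from 13.9 to 5.93 CPM (log2 fold change -1.23 ± 0.18). The matrix peroxidase gene Pxdn fell from 131 to 83.3 CPM (log2 fold change -0.66 ± 0.09). The phosphatase gene Acp1 and the activity-regulated synaptic gene Nptx2 had log2 fold changes of -0.53 ± 0.07 and -0.52 ± 0.07. As the naming rule required, the 4 cKO libraries did not overlap the 4 control libraries for any of these genes, and the remaining lower gene was Gm9493. With 1 library left out at a time, Prm1, Egfl6, Hopx and Fopnl passed in all 8 fits. Agt missed the threshold without cKO 1 (edgeR adjusted p = 0.0543), Ccl3 missed it in 3 fits, and Alox8, Spp1, Tfcp2l1, Pxdn, Acp1 and Nptx2 each missed it in 6 to 8 fits. In the authors' deposited table all 16 genes had a q-value under 0.05, among 127 genes with such a value.

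**Figure D1:**
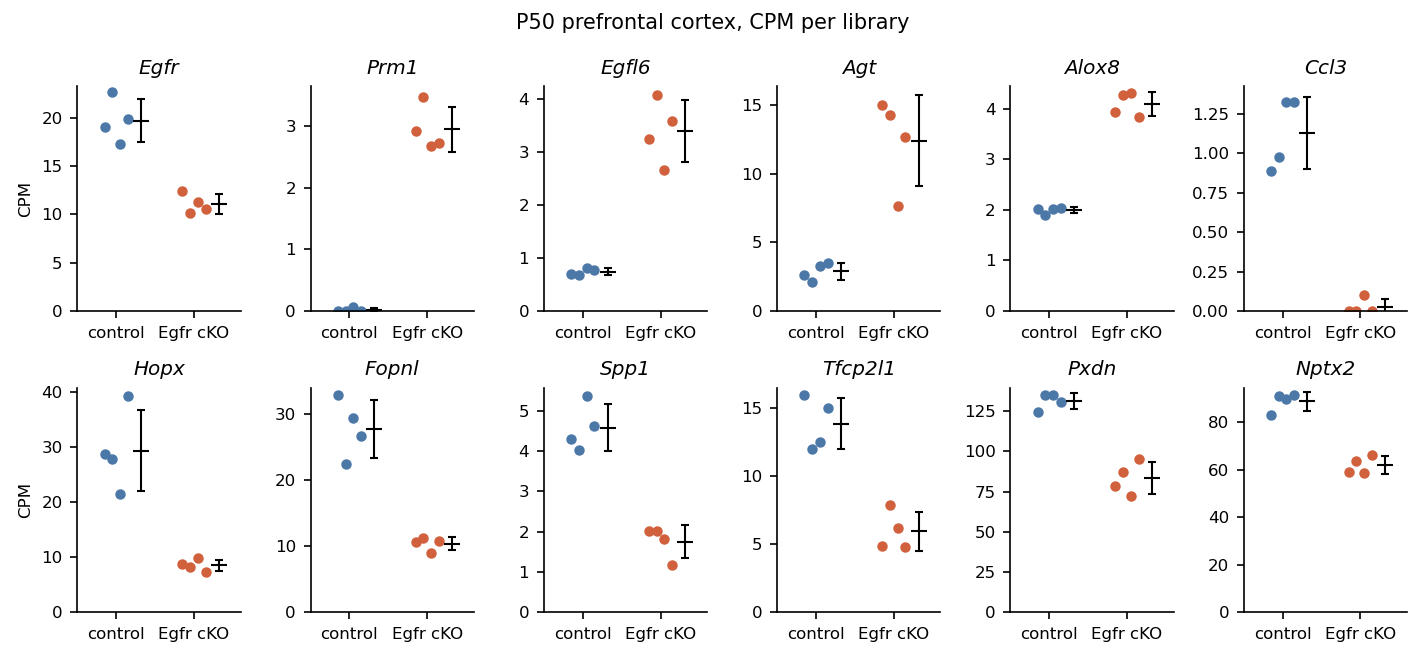
CPM on the vertical axis for 12 genes in each P50 library (points), with the mean and SD of 4 libraries per group beside them. Egfr averaged 19.7 CPM in control and 11.1 CPM in cKO. The groups did not overlap for any gene shown, which the naming rule required of all but Egfr.

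A second question at P50 was whether sets of glial, neuronal or immune genes moved together. Complement and interferon genes had the clearest shift: all 19 tested members were higher in cKO, with a median log2 fold change of 0.54. Rtp4, Ifitm3, C4b, Ifit1, Irf7, Ifit3, B2m, Isg15, Usp18 and C1qb, 10 of the 19, passed with edgeR adjusted over the list alone. None passed with edgeR over all genes tested. With DESeq2 over all genes, Ifitm3 (DESeq2 adjusted p = 0.000217), Rtp4 (0.00234) and C4b (0.00431) passed. By limma's camera with a preset correlation the list had an adjusted p of 1.39e-12, and adjusted p = 0.337 with an estimated correlation. Library cKO 3 was highest on it, with a mean centred log2 CPM of 0.64 against 0.12 to 0.28 in the other cKO libraries. Mitochondrial counts were 20.2% in cKO 3 and 7.39% to 12.7% in the other libraries. Without cKO 3 the difference between group means of log2 CPM on this list went from 0.60 to 0.49. Meningeal fibroblast markers had a median log2 fold change of 0.98, with 13 of 14 higher (limma camera, adjusted p = 0.638 with an estimated correlation). On this list control 9 (mean centred log2 CPM 0.34) lay above cKO 3 (0.30) and cKO 5 (-0.06). Control 11 and control 12 were lowest, at -0.95 and -0.97. Astrocyte markers had a median of 0.24, with 20 of 25 higher (limma camera, adjusted p = 0.638 with an estimated correlation), and only Agt passed adjusted over the list alone. Their mean centred log2 CPM was -0.08 in cKO 5, against 0.10 to 0.26 in the other cKO libraries and -0.21 to 0.06 in control. Myelin and oligodendrocyte genes had a median of -0.56, with 1 of 24 higher (limma camera, adjusted p = 0.718 with an estimated correlation). For these genes the difference between group means of log2 CPM went from -0.56 to -0.20 without cKO 2 and to -0.36 without control 11. Of the 36 lists, 16 passed with the preset correlation and 0 with the estimated one. Among immediate early genes Fos, Junb, Nr4a1, Egr4 and Jun were higher and Nptx2 and Bdnf lower, adjusted over the list alone. Over all genes tested only Nptx2 of these passed with edgeR, and Nptx2, Fos and Junb passed with DESeq2. Library cKO 5 stood apart on the immediate early list, with a mean centred log2 CPM of -0.25 against 0.16 to 0.27 in the other cKO libraries. Control libraries had -0.28 to 0.06 on it. Library cKO 5 also stood apart on dissociation stress genes (-0.11 against 0.11 to 0.29 in the other cKO libraries).

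At P2 the first question was whether Egfr transcript fell in the cell classes that carry it. Egfr fell in glial intermediate progenitor-like cells from 266 to 78.6 CPM, a cKO over control ratio of 0.296 (95% interval 0.246 to 0.353, counting error only, as for every P2 interval). In cycling cells Egfr went from 164 to 55.9 CPM (ratio 0.340, 0.305 to 0.378). In the largest cluster of radial glia or astrocytes, which its markers did not tell apart, Egfr went from 39.3 to 10.1 CPM (ratio 0.257, 0.195 to 0.335). Astrocyte-like cells kept more of it, at 212 CPM in control and 121 CPM in cKO (ratio 0.571, 0.493 to 0.660). The reads are 3′ tags, which need not cover the deleted part of Egfr, and Egfr was itself among the markers of glial intermediate progenitors.

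Prm1 was found at P2 as well, with 0 UMIs in the control library and 13885 in the cKO library. Its level in cKO was 970 CPM in the largest cluster of radial glia or astrocytes, at least 2334-fold higher than a floor of 3 UMIs in that control class. Prm1 was highest in the radial glia-like class, at 1541 CPM, where Egfr did not differ detectably (11.7 CPM in control, ratio 1.03, 0.596 to 1.77) and most cKO cells came from a cluster absent from control. Prm1 stood at 268 CPM in glial intermediate progenitor-like cells, 184 CPM in astrocyte-like cells, 17.2 CPM in upper-layer pyramidal neuron-like cells and 13.4 CPM in microglia-like cells. In the largest cluster of radial glia or astrocytes 92.8% of cKO cells had a Prm1 UMI (median depth 8923 UMIs), against 11.3% of microglia-like cells (median depth 9529 UMIs).

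**Figure D2:**
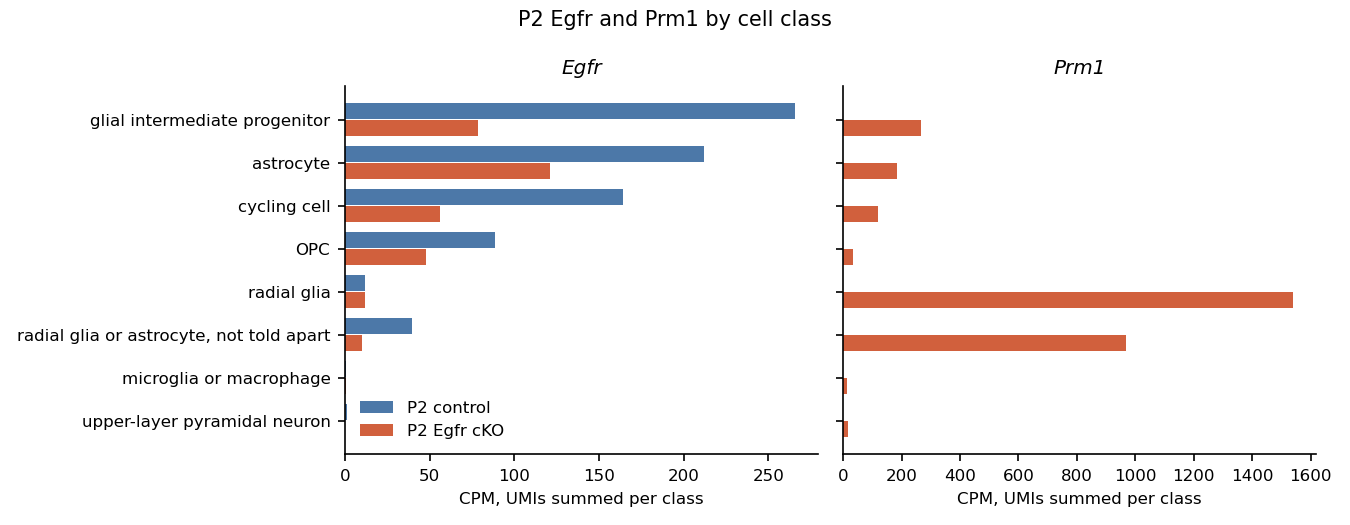
Egfr (left) and Prm1 (right) in CPM of UMIs summed per P2 cell class, 1 library per genotype (bars). Egfr in glial intermediate progenitor-like cells was 266 CPM in control and 78.6 CPM in cKO, and Prm1 reached 1541 CPM in cKO radial glia-like cells.

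The next question was which cell classes made up the sorted P2 cells of each genotype. Astrocyte-like cells were 6.36% of control cells (573 of 9014, 5.86 to 6.88) and 2.10% of cKO cells (109 of 5187, 1.73 to 2.53), a ratio of 0.331 (0.267 to 0.406). OPC-like cells, the precursors of oligodendrocytes, were 1.62% and 0.636% (ratio 0.393, 0.261 to 0.576), with a log2 ratio that ran from -2.57 to -0.46 over the alternatives (-1.35 here). Glial intermediate progenitor-like cells were 4.46% and 2.91% (ratio 0.653, 0.538 to 0.789), and this direction flipped in 2 of the alternative clusterings. All radial glia and astrocyte clusters summed were 21.1% of control cells and 21.4% of cKO cells (ratio 1.02, 0.943 to 1.10). With each cell named by its highest marker score in place of its cluster, the astrocyte log2 ratio moved from -1.60 to 0.22. Upper-layer pyramidal neuron-like cells were 49.0% and 50.1% (ratio 1.02, 0.973 to 1.07). Within this class a cluster led by Nrgn, Mef2c and Nefl went from 6.13% (553 control cells) to 0.790% (41 cKO cells). None of its 10 leading genes was an upper-layer marker, and Rprm among them is on the deep-layer list, so its name is in doubt. Pyramidal intermediate progenitor-like cells were 2.56% and 4.05% (ratio 1.58, 1.30 to 1.91), but the log2 ratio of 0.66 fell to between 0.11 and 0.28 in 6 alternatives and to -0.0075 in another. Radial glia-like cells came from different clusters in the libraries: 1 with 283 control and 45 cKO cells, and 1 with 208 cKO cells and 0 control cells led by Prm1, Cdkn1a and Phlda3. The fall was not limited to glia: Cajal-Retzius-like cells were 1.11% and 0.328% (100 and 17 cells, ratio 0.295, 0.166 to 0.497), with ratios of 0.0874 to 0.615 over the alternatives. Mural cells numbered 31 in control and 0 in cKO, but 40 and 13 with doublet calls kept and 33 and 17 with cells of 500 or more genes and under 20% mitochondrial UMIs, so their absence depended on the filters. These shares are of cells that passed a fluorescence sort, which can itself set them. The labels call the sorted cells tdTomato-positive after a FlashTag dye injection at E18 and name no reporter allele, so whether the gate followed a reporter or the dye is open.

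**Figure D3:**
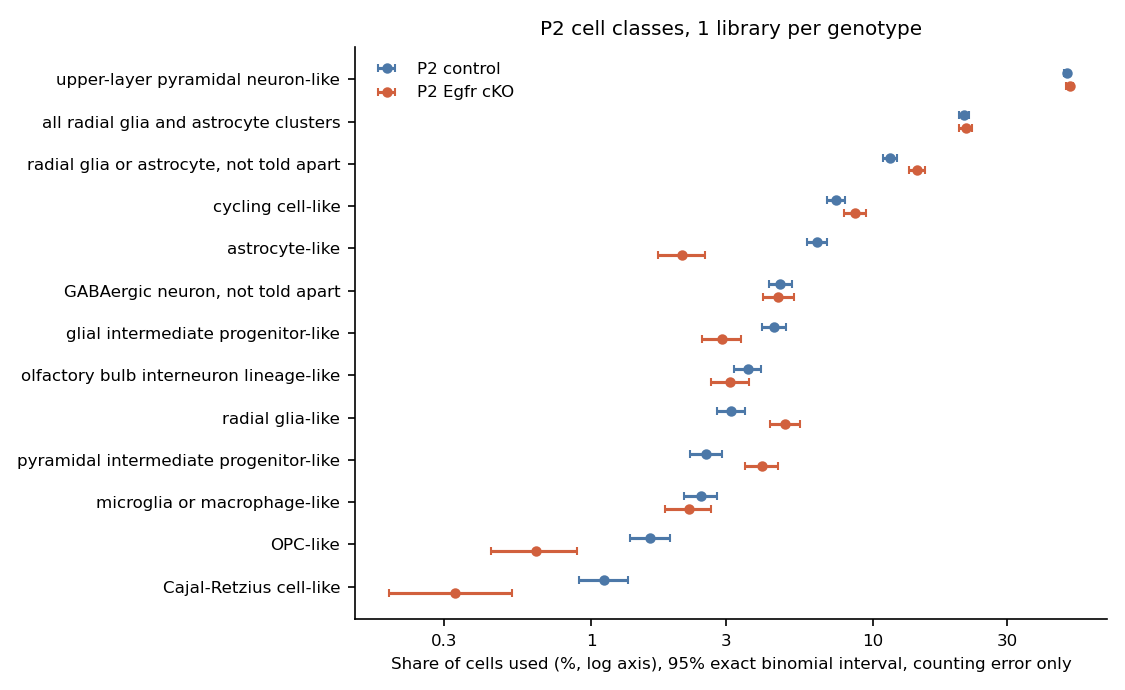
Share of P2 cells in each class on a log axis in percent, with exact binomial 95% intervals (bars) for the control and Egfr cKO libraries. Astrocyte-like cells were 6.36% of control cells and 2.10% of cKO cells, while radial glia and astrocyte clusters together were 21.1% and 21.4%.

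Within glial intermediate progenitor-like cells, genes of the oligodendrocyte lineage, immediate early genes and ERK pathway response genes were mostly lower in cKO. Bcas1, an early oligodendrocyte gene, had 105 UMIs in control and 0 in cKO, at least 16.1-fold lower. Pdgfra, the receptor gene that marks OPCs, went from 52.4 to 6.69 CPM (ratio 0.128, 0.0649 to 0.228). Egr1, an immediate early gene downstream of ERK, went from 847 to 23.4 CPM (ratio 0.0277, 0.0199 to 0.0375), and Junb from 142 to 21.2 CPM. Cdkn1c went from 130 to 10.6 CPM. Eomes, a gene of the neuronal lineage, rose from 42.9 to 159 CPM (ratio 3.71, 3.05 to 4.51), and Cdkn1a rose from 30.6 to 142 CPM. All 9 OPC markers measured were lower, with a median log2 ratio of -2.17, and all 15 immediate early genes were lower, with a median of -1.76. ERK pathway response genes had a median of -0.87, with 16 of 18 lower. Gliogenesis transcription factors had a median of -0.55, and cell cycle genes a median of 0.69 with 13 of 13 higher. Dissociation stress genes, which share members with the immediate early genes, had a median of -0.80. All 13 mitochondrially encoded genes were lower, with a median of -0.33. The fall was not limited to these lists, as interneuron markers had a median of -1.05 (7 of 8 lower) and deep-layer neuron markers of -0.85 (6 of 9 lower). Each of these medians lay outside the middle 95% of 10000 random lists matched on expression. That range is too narrow for genes that vary together, since random members were drawn 1 by 1. In this class 14 lists lay outside it, against 1 of 24 unchanged lists in simulated sums with independent genes. The border of this class with OPCs moved with the clustering (146 control OPC-like cells here, 340 at resolution 2), so control cells near that border can carry part of the lower OPC genes. In the class as named at resolution 2 the OPC median was -0.38, the immediate early median -0.82 and the mitochondrial one 0.03. Clustering without Prm1, Xist and Y-linked genes gave -0.76 for OPC markers, -1.70 for immediate early genes, 0.19 for mitochondrial genes and -0.23 for cell cycle genes, the last a change of direction.

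Astrocyte-like cells shared part of that pattern, mostly with smaller medians. Outside the random range, OPC markers had a median log2 ratio of -0.37, immediate early genes -0.24, dissociation stress genes -0.12, gliogenesis transcription factors -0.46 (13 of 14 lower) and cell cycle genes 0.55 (12 of 13 higher), while ERK pathway response genes had a median of 0.01, inside the random range. Astrocyte markers were lower in these cells, with a median of -0.11 and 16 of 23 lower. With cells thinned to 2000 UMIs only the OPC and gliogenesis lists, of those named here for astrocyte-like cells, lay outside the random range, the dissociation stress median became 0.08, and complement and interferon genes had too few UMIs for a value. Complement and interferon genes were higher in astrocyte-like cells, with a median of 0.77 and 9 of 11 higher. In the largest cluster of radial glia or astrocytes, astrocyte markers had a median of 0.28, with 18 of 22 higher, while excitatory neuron markers had a median of -0.68 (8 of 9 lower), interneuron markers of -0.77 (10 of 11 lower) and GABA-A receptor subunits of -0.39. Genes of astrocyte transmitter uptake and potassium buffering were higher there in 14 of 14 cases, with a median of 0.37. Cholesterol synthesis genes were higher in 22 of 22 cases, with a median of 0.41. In that cluster ERK pathway response genes were higher too, with a median of 0.22 and 14 of 18 higher, although Egfr fell there. OPC markers had a median of 0.46 there, with 5 of 9 higher, which became -0.32 in thinned cells. RNA released by neurons was not tested as a source of the lower neuronal lists here or in glial intermediate progenitor-like cells. Cck, a leading gene of some upper-layer neuron clusters, was lower in cKO in all 9 classes compared. In microglia-like cells it had 11.4 CPM in control and 3.56 CPM in cKO.

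Neurons and microglia showed other differences between the P2 libraries. In upper-layer pyramidal neuron-like cells the neuropeptide gene Npy went from 62.8 to 2.85 CPM (ratio 0.0453, 0.0334 to 0.0601). The neurotrophin gene Ntf3 went from 36.1 to 2.26 CPM, and the lipase gene Lpl from 52.1 to 4.24 CPM. GABA-A receptor subunits had a median log2 ratio of -0.69 there, excitatory neuron markers of -0.54, cholesterol synthesis genes of -0.40 and ionotropic glutamate receptors of -0.24, all below the random range. Much of this came with a cluster led by Nrgn, Mef2c and Nefl, with 553 control and 41 cKO cells. Without it Npy had 3.27 and 1.44 CPM (ratio 0.441, 0.262 to 0.718), and the ratios were 0.428 (0.177 to 0.938) for Ntf3 and 0.464 (0.226 to 0.896) for Lpl. The medians without it were 0.14 for GABA-A subunits, -0.06 for excitatory neuron markers and 0.03 for glutamate receptors, inside the random range, and 0.16 for cholesterol synthesis genes, now above it. In microglia-like cells Lgals3 went from 179 to 43.6 CPM and Gpnmb from 176 to 44.5 CPM, while Cxcl10 rose from 29.8 to 256 CPM. Immediate early genes and dissociation stress genes were both higher in cKO microglia-like cells, with medians of 0.61.

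**Figure D4:**
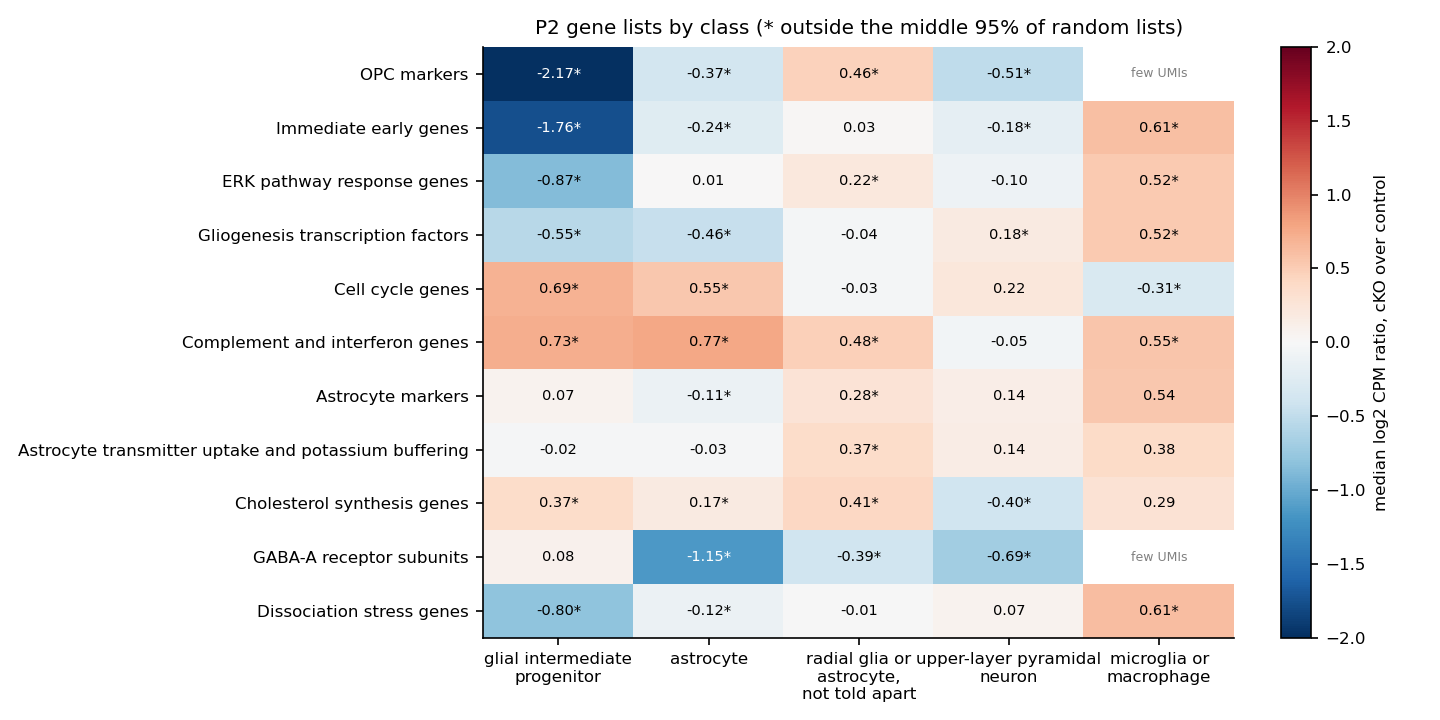
Median log2 CPM ratio of cKO over control for 11 gene lists (rows of tiles) in 5 P2 cell classes (columns), where an asterisk marks a median outside the middle 95% of random lists. OPC markers had a median of -2.17 in glial intermediate progenitor-like cells and immediate early genes had -1.76.

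The last comparison asked in which P2 control cells the P50 genes were concentrated. Egfr was left out, since it was the deleted gene and a marker of glial intermediate progenitors. By two-sided Fisher's exact test none of the classes then passed in either direction (smallest adjusted p = 0.449, with 3 at an unadjusted p under 0.05). Only 4 higher and 9 lower genes entered this test, so it could miss a concentration. With Egfr counted, genes lower at P50 passed in glial intermediate progenitors on Egfr and Nptx2 alone. At an unadjusted p under 0.05 in place of the calls, 602 higher and 417 lower genes entered. Higher genes then passed in endothelial (Fisher adjusted p = 7.65e-19), radial glia (4.14e-18), astrocyte (2.49e-12) and microglia (2.69e-08) classes and the largest radial glia or astrocyte cluster (0.00198). Lower genes passed in cycling cells (0.000228) and OPCs (0.0202). The test treats genes as independent, but genes of a class can vary together. Hopx, lower at P50, was lower at P2 in astrocyte-like cells (330 and 222 CPM, ratio 0.671, 0.601 to 0.748) and in the largest cluster of radial glia or astrocytes (1261 and 1184 CPM, ratio 0.939, 0.911 to 0.967). Its direction differed by class, with ratios of 1.63 (1.53 to 1.74) in radial glia-like cells, most of which in cKO came from a cluster absent from control, 1.25 (1.14 to 1.36) in cycling cells, 1.19 (1.05 to 1.35) in glial intermediate progenitor-like cells and 1.24 summed over all radial glia and astrocyte clusters. Ccl3, lower at P50, was higher in P2 cKO microglia-like cells (611 and 1203 CPM, ratio 1.97, 1.83 to 2.12), and Spp1 was too (2024 and 3365 CPM). This class includes a cluster of 16 cKO cells and 0 control cells, and without it the ratios were 2.01 for Ccl3 and 1.72 for Spp1. Agt had 3 or fewer UMIs in either library's radial glia and astrocyte clusters, too few for a comparison. Fopnl did not differ detectably there at P2 (60.1 CPM in both libraries, ratio 1.00, 0.906 to 1.11).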

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

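The tests of explanations for Prm1, the astrocyte share and the p53 targets were chosen after the results had been seen, and the 5% bound on the counts of splits was written down only then too. Of 34 groups of 4 libraries, 2 held a library far from the others, and chance gives about 1 in 20. Prm1 stood at 0.0577 CPM in control 11 and 0 in the other control libraries, and Ccl3 at 0.0990 CPM in cKO 3 and 0 in the other cKO libraries. Both rest on 1 or 2 counts.

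Signals outside the comparisons concerned sex. Library cKO 5 at P50 had 2849 Y-linked counts and 40 Xist counts, while each of the other 7 libraries had at most 8 Y-linked counts. At P2, 2062 cKO cells (39.8%) had Y-linked UMIs and no Xist, against 1 control cell. The P2 cKO library therefore held cells of male and female animals and the control library almost none of male ones.

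The number of genes past the threshold at P50 exceeded what other groupings gave: of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one with 16 genes, gave as many, and the highest other gave 6. Chance is not excluded for the gene lists, since 4 of the 35 splits gave 16 lists or more and the highest other gave 17.

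Prm1 in the cKO cells was the first pattern weighed. RNA released by other cells was argued against, since 92.8% of cells in the largest cluster of radial glia or astrocytes had a Prm1 UMI, against 11.3% of microglia-like cells at a similar depth. Opening of the whole gene cluster was argued against by 0 UMIs of Prm2, Prm3 and Tnp2. A transcript of the Cre transgene that carries Prm1 sequence stays open: Egfr in cKO cells with a Prm1 UMI over those without had a ratio of 0.336 (0.175 to 0.709) within that cluster and 0.391 (0.256 to 0.577) within astrocyte-like cells, but of 0.911 (0.640 to 1.31) within glial intermediate progenitor-like and 0.826 (0.677 to 1.01) within cycling cells. The prediction for such a transcript was a lower Egfr in cells with a Prm1 UMI, beyond counting error, within every class compared. It held within that cluster and astrocyte-like cells, and failed within glial intermediate progenitor-like and cycling cells. The test cannot decide either way, since descendants of recombined cells can lack Egfr with or without a Prm1 UMI. A response of Prm1 to loss of Egfr cannot be told apart from such a transcript, because Cre and Egfr loss come together. The 7.62% of cKO upper-layer neurons with a Prm1 UMI lay below the share in microglia-like cells and decides nothing.

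The lower share of astrocyte-like cells was the second pattern. Depth was argued against by a log2 ratio of -1.55 with cells thinned to 2000 UMIs, and sex by -1.86 with only the cKO cells that had Xist and no Y-linked UMI. The line drawn between radial glia and astrocytes stays open as the cause, since naming each cell by its highest marker score gave a log2 ratio of 0.22. Variation between animals was not tested, with 1 library per genotype.

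Raised p53 target genes were the third pattern: in the cKO radial glia and astrocyte clusters together, the 30 measured targets had a median log2 ratio of 1.19, with 27 higher, but the list was written after Cdkn1a and Phlda3 had been seen to lead a cluster of 208 cKO cells and 0 control cells, and without that cluster 26 targets had a median of 0.21. The median was 0.03 in the largest of these clusters and 0.80 in glial intermediate progenitor-like cells. Dissociation stress was argued against, since its list lay at percentile 16.6 in the clusters together. Some of the pooled animals may be the source: the median was 0.39 in cKO cells with Y-linked UMIs and no Xist, and 1.79 in cells with Xist alone, and sex itself stays open too. An effect of Cre or the transgene cannot be told apart from loss of Egfr, as cells with a Prm1 UMI had a median of 1.28 and no control cell had Prm1. Those cells include 98.4% of the cKO radial glia-like cells, most of them from the cluster of 208. In the largest cluster the 694 cells with a Prm1 UMI, with Egfr at 9.05 CPM, had a median of 0.02. The 54 cells without it had 0.34. With and without a Prm1 UMI the medians were 0.92 and 0.37 in glial intermediate progenitor-like cells, and 0.76 and 0.15 in astrocyte-like cells.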

How the results depend on the processing

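The settings chosen only after the data had been seen were library sex as a covariate, mitochondrially encoded genes left out, clustering without Prm1, Xist and Y-linked genes or p53 targets, tied names left out, the cKO cells split by Xist and Y-linked UMIs, the cluster led by Nrgn left out, Egfr left out of the concentration test, the microglia cluster of 16 cKO cells left out, and lists in glial intermediate progenitors as named by the other clusterings. No paired analysis was possible because the bulk columns carry no labelled replicate numbers.

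The 13 named P50 genes kept their direction in all 255 values under alternatives and stayed past the threshold in 169 of them. The naming rule required no overlap between groups for all but Egfr, so a change of direction was unlikely. Egfl6, Fopnl, Hopx and Prm1 passed under every alternative that gave a value. Egfr lost its call in 11 of 20 alternatives, with edgeR, limma or DESeq2 adjusted p from 3.73e-07 to 0.120. Its log2 fold change was -0.81 with limma on log2(FPKM + 0.1), with or without the FPKM filter, -0.48 with a pseudocount of 1, which shrinks folds of low genes, and -0.80 with sex as a covariate. Leaving out 1 library gave -0.89 to -0.75, with edgeR adjusted p from 0.0472 (without control 11) to 0.120 (without control 12), where fewer samples remain.

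The 6 higher and 10 lower genes became 88 and 35 with DESeq2 (71.5% higher, against 37.5%), and the 16 edgeR genes were among these 123. At an unadjusted p under 0.05 there were 725 and 463. A minimum of 5 CPM, which tests fewer genes, gave 3 higher genes. Lower genes numbered 6 with library totals, 4 with limma on log2(FPKM + 0.1), 5 with a pseudocount of 1 and 6 with sex as a covariate. Leaving out 1 library gave 3 to 9 higher and 2 to 12 lower genes. The higher count was 3 without cKO 1. The lower count was 4 without control 10, control 11, cKO 2 or cKO 3, 6 without cKO 5, and 2 without control 12 or cKO 1. The number of lists fell from 16 to 0 with an estimated correlation and to 0 with fry directional. For these 16 lists the estimate ran from 0.033 (astrocyte-derived synapse factors) to 0.86 (myelin and oligodendrocyte genes), above the preset 0.01. With 1 library left out the number of lists ran from 9 (without cKO 2) to 17. Except where stated, the cause was not tested.

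The astrocyte log2 ratio of -1.60 stayed between -1.86 and -1.13 except with the highest marker score per cell, where it was 0.22. The value of -1.13 came from cKO cells with Y-linked UMIs and no Xist. The glial intermediate progenitor ratio of -0.62 became 0.28 in thinned cells, 0.84 without Prm1, Xist and Y-linked genes, -1.64 with the marker score and -0.90 in cKO cells with Xist alone. The OPC ratio of -1.35 became -2.48 at resolution 2, -2.57 in thinned cells, -0.46 without p53 targets, -2.25 in cells with Xist alone and -0.74 in cells with Y-linked UMIs alone. The pyramidal intermediate progenitor ratio of 0.66 became -0.0075 with 1500 genes and 5% mitochondrial UMIs, 0.23 with 500 genes and 20%, 0.12 at resolution 0.5, 0.13 in thinned cells, 0.11 with centred components, 0.20 with doublets kept and 0.28 without p53 targets. The cycling cell ratio of 0.23 became -0.13 in cells with Xist alone and 0.78 in cells with Y-linked UMIs alone. All radial glia and astrocyte clusters moved from 0.02 to 0.21 at resolution 2, 0.22 in cells with Xist alone and 0.15 with the marker score. The upper-layer ratio of 0.03 became -0.11 at resolution 2, -0.043 without Prm1, Xist and Y-linked genes, -0.062 in cells with Xist alone, 0.12 with the marker score and 0.12 without the cluster led by Nrgn. The radial glia ratio became -1.06 in cells with Y-linked UMIs alone. The cause was not tested, and classes with no cluster of that name under a setting gave no value.

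Egfr had a log2 ratio of -1.87 in thinned cycling cells (-1.56 before) and -2.85 in pyramidal intermediate progenitors with 500 genes and 20% mitochondrial UMIs (-0.79 before). The value of -0.79 rested on 8 control and 5 cKO UMIs of Egfr, so a few UMIs can move it. Of 1910 values of named P2 genes, 27 reversed. In thinned cells these were Ebp (-0.14) and Neurod6 (0.51) in astrocytes, Emp1 (-0.17), Has2 (-1.24) and Stard4 (0.49) in cycling cells, Rrm2 (-1.59) in microglia, Rtp4 (-0.010) in the largest cluster of radial glia or astrocytes and Zfp36l1 (-0.56) in the olfactory bulb lineage. With 500 genes and 20% mitochondrial UMIs these were Psmb8 (-0.67) in cycling cells, and mt-Nd4l (-0.025) and mt-Nd6 (-0.23) in pyramidal intermediate progenitors, where mt-Nd6 was also reversed with doublets kept (-0.15). Without the microglia cluster of 16 cKO cells these were Nfib (-0.0036), Nfia (-0.23) and Zbtb20 (-0.52) in microglia. Without the cluster led by Nrgn these were Lhfpl3 (0.36), Slc30a3 (0.039), Sv2b (0.36), Kitl (0.085), Grin3a (0.74), Gabrg1 (0.85), Stx1a (0.11), Vgf (0.19), Idi1 (0.11), Hmgcs1 (0.15), Msmo1 (0.15) and Etv5 (0.14) in upper-layer neurons. Lists outside the random range fell in thinned cells from 13 to 3 in astrocytes, from 14 to 9 in glial intermediate progenitors and from 18 to 11 in all radial glia and astrocyte clusters, where thinning leaves fewer genes measured. Without the cluster led by Nrgn they fell from 14 to 7 in upper-layer neurons. The concentration of P50 genes, 1 class and direction in the report, became 0 with Egfr left out or with 2 times the CPM, and 7 with genes at an unadjusted p under 0.05. The cause was not tested.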

Other observations

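The test of the hypothesis in this part was chosen, and its prediction written, after the result had been seen. The cKO cells that became astrocyte-like may come mostly from cells that kept Egfr. Of cKO astrocyte-like cells 30.3% had a Prm1 UMI (median depth 15668 UMIs), against 92.8% in the largest cluster of radial glia or astrocytes (median depth 8923 UMIs) and 11.3% of microglia-like cells (9529 UMIs). Egfr was 147 CPM in cKO astrocyte-like cells without a Prm1 UMI, 57.6 CPM in those with 1, and 212 CPM in control. Pooled, these values fit the hypothesis, but Prm1 as a mark of Cre is itself unproven. The Prm1 share was 61.1% in the 36 cKO astrocyte-like cells with Xist alone and 15% in the 60 with Y-linked UMIs alone. Egfr was 90.7 and 131 CPM in these cells. In the largest cluster of radial glia or astrocytes the shares were 99.2% and 89.4%. The predicted drop in share held for cells with Y-linked UMIs alone and not for cells with Xist alone. Depth does not account for the lower Prm1 share, as the astrocyte-like cells were the deeper ones.

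In each of 9 classes, microglia included, 21 genes differed in the same direction between the P2 libraries, 12 higher and 9 lower in cKO. Those named here were chosen after their values had been seen. Gm10709 went from 354 to 1.78 CPM in microglia-like cells, Lamtor3 from 52.6 to 16.9 CPM and Tpm3-rs7 from 299 to 185 CPM, while Tpm3 rose from 225 to 439 CPM. At P50 Tpm3 had a log2 fold change of 0.38 ± 0.28 (SE) and Tpm3-rs7 of -0.33 ± 0.37, neither past the edgeR threshold. Copies of near-identical sequence, as among Tpm3 and Tpm3-rs7, can exchange reads. Gm10260 had 8 UMIs in control and 4118 in cKO, Gm5900 had 5 and 2917, and Gm10709 had 18910 and 80. None of the 19 genes tested at P50 passed the edgeR threshold. Gm10260 and Gm5900 had P50 log2 fold changes of -0.48 ± 0.63 and -0.41 ± 0.17 (SE). Cwc22, lower in P2 cKO (9702 UMIs in control and 3091 in cKO), had the largest P50 change of the 19. Its P50 log2 fold change was -3.60 ± 1.00 (SE), the same direction as at P2 (edgeR adjusted p = 0.363). A difference between the P2 libraries apart from Egfr was not tested and would bear on every P2 ratio.

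Among the 16 genes past the threshold at P50, Egfr, Ccl3, Alox8 and A830036E02Rik lay on chromosome 11 (25% of them, where 7.92% of tested genes lie). Chromosome 5 held Hopx, Nptx2 and Spp1 (18.8% against 6.61%), chromosome 16 Prm1 and Fopnl (12.5% against 3.07%), and chromosome 12 Pxdn and Acp1 (12.5% against 3.48%), 876 kb apart. These positions were looked at after the genes were known and were not tested.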
